A study of Homo sapiens and Mus musculus with 10 samples.

How the data were processed

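Gene expression was measured by bulk RNA-seq in A549 and 4T1 cells. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit, which as named does not mark strand. The A549 libraries fall into control (n = 3) and ZNF296 overexpression (n = 3), and the 4T1 libraries into non-targeting guide (n = 2) and Zfp296 guide (n = 2), each taken from the sample titles. Another line, MDA-MB-453, is named in the extraction protocol and was not analysed here. The labels call the A549 control wild type, while the aligned reads named in the file headers carry the name of an empty lentiviral vector, pLVX-Puro, so whether the control cells carried the vector is not settled.

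All values used were raw counts as deposited. Per the file headers, the A549 counts are read pairs over exons summed by gene identifier, made with featureCounts 2.0.1 in paired mode, with no strand option, on the Ensembl GRCh38 release 95 annotation. The submitters' processing notes name HISAT2 2.2.1 and featureCounts 2.0.6 and the builds mm9, GRCh38 and hg38, so the counter's version differs between these sources. The deposited 4T1 counts are 1 table of whole numbers by gene symbol, in which 0 of the 13 mitochondrially encoded genes looked for were found, and their annotation is not given in the sources used here. No coordinates are printed for mouse genes. Each A549 file held 58735 gene identifiers, all of which were found in GENCODE 29, used for symbols and positions, and the 4T1 table held 25239 symbols. No column was left unused and 0 entries named no gene. Counting without strand cannot separate a gene from an antisense or overlapping partner. Of 111 named A549 genes checked against GENCODE 29, 1 (RNF43) shares over 25% of its exon bases with another gene. Genes with near-identical copies can share reads. Some such cases are given as uncertain, but genes were not screened for copies, so unmarked genes may be affected too.

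Library totals were 17360074, 18251629 and 17905140 counts in A549 controls, 19150465, 19542690 and 18055895 in overexpression, 30986175 and 33697861 in sgNTC and 30745235 and 30214849 in sgZfp296-1. Genes with at least 1 count numbered 24733 to 24983 in A549 controls and 23759 to 23949 in overexpression, and 14254, 14426, 15393 and 14642 in the 4T1 libraries in the order given. Replicates were compared by a chi-square of their counts over genes. This gave 2.27 to 17.6 per degree of freedom within A549 groups and 5.42 and 4.00 within 4T1 groups, so no pair agreed within sampling noise and each library counts once.

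Each line was fitted alone with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr, libraries were scaled by TMM, and group differences were tested with the robust quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested, called changed under 0.05. TMM factors were 1.074 to 1.101 in A549 controls and 0.876 to 0.951 in overexpression, and 0.988 to 1.01 in 4T1. The median log2 fold change over all genes was 0.000821 in A549 and -0.00161 in 4T1, and 0.0113 and -0.000236 with DESeq2's size factors. Both scalings take most genes as unchanged, while 70.2% of A549 genes were called. A shift shared by most genes would not be seen, and the balance of higher and lower calls depends on the scaling. The biological coefficient of variation was 0.0796 and 0.0498. CPM values are TMM-scaled, with mean ± SD over libraries. Fold changes are perturbed minus control, where perturbed means overexpression in A549 and knockdown in 4T1. All adjusted p-values of single genes come from this test unless another is named.

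Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, an inter-gene correlation preset to 0.01 and Benjamini-Hochberg adjustment over the lists with at least 5 tested members, 26 in A549 and 22 in 4T1. Camera compares a list with the other genes. It was repeated with the correlation estimated from the residuals. That form also takes its degrees of freedom from the few libraries (2 residual in 4T1), so a list can fail it even where its correlation is low. Beside it the rotation test fry was run, whose p tests whether a list's genes move on balance one way. Its mixed p tests change in either direction. Neither of these compares the list with other genes. The 26 lists cover interferon-stimulated genes, interferon receptor signalling, nucleic acid sensing, MHC class I and class II antigen presentation, chemokines, secreted cytokines and growth factors, immune checkpoint and killer-cell ligands, NF-kB, p53, NRF2 and WNT targets, mesenchymal and epithelial genes, proliferation, integrated stress and unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, chromatin repressors, pluripotency, markers of the tissue of origin, of leukocytes and of fibroblasts and endothelium, immediate-early and heat shock genes, mitochondrially encoded genes (0 in the 4T1 table) and ribosomal proteins. Some genes stand in more than 1 list. Across lines, genes were paired by identical symbol regardless of case, and the overlap of calls was compared with independent lists by Fisher's exact test (two-sided).

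The tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule takes the target gene with each library's value. It takes the 8 higher and 8 lower genes with the largest absolute log2 fold change among those called, with a mean of at least 5 CPM in the higher group and no overlap of libraries, leaving out unnamed loci and pseudogenes. From each list it takes up to 4 called members in order of p, at most 3 of them in 1 direction where both occur. Across lines it takes up to 8 genes called in opposite directions with the largest smaller absolute change, plus the other line's value of genes already named. Not all genes the rule allows are printed, some are not reported here, and the genes plotted for interferon response and chemokines were chosen after their values were seen.

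Alternatives set beforehand were DESeq2's size factors, DESeq2 1.42.0 itself, no filter on low counts, a filter at 1 CPM, a minimum absolute log2 fold change of 1, the replicate number as a block, each library left out in turn, and the other list tests. In 4T1, leaving out a library leaves a lone sample, which is assumed to vary like the other group. After the data were seen, an offset per library for the trend with transcript length and GC content was added. It was fitted with natural splines (4 degrees of freedom each for log2 length and GC content) on genes with a mean log2 CPM above 1, without the ribosomal protein and mitochondrial lists. Length and GC came from the gene's longest protein-coding GENCODE 29 transcript, or its longest of any type where it had none. They were found for 99.95% of tested A549 genes, and from the human gene of the same symbol for 87.21% of tested 4T1 genes. Of 2 forms computed, the one centred per library was kept, a choice made after the uncentred form had been run and its values seen. The uncentred form gave 9660 changed genes in A549 (4921 higher, 4739 lower) and 4535 in 4T1 (1844 higher, 2691 lower, 40.7% higher against 49.1% centred), a median of 0.517 for A549 ribosomal protein genes and of 0.347 for mitochondrially encoded genes.

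Where a group held 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of counts per library size is given with its 95% counting interval. List medians with such genes at their bound were the same as the fitted ones. These intervals and floors cover counting error only. The procedure was tested on simulated counts with 200 changed genes, besides the chemokine list, which was lowered by 1 on the log2 scale. Genes were drawn independently and few were changed. Scaling error and correlation between genes in the real data were therefore not tested. The 200 changed genes all had at least 5 CPM in control and lay outside the lists, so recovery of lower genes was not tested. Every gene was given the dispersion of the trend at its level, so genes with an unusual spread were not simulated either. In the A549 simulation (15848 genes) 96% of 1.5-fold and 100% of 2-fold, 4-fold and 8-fold changes were recovered and 13 of 15635 unchanged genes were called. In the 4T1 simulation (12139 genes) 98.5% of 1.5-fold and 100% of the larger changes were recovered and 10 of 11930 unchanged genes were called. With a trend in length added, the same in every perturbed library, 8435 and 6389 unchanged genes were called without the offset. With it 22 and 15 were called, and 90% and 90.8% of 1.5-fold changes were recovered. No GC trend was simulated, so the GC part of the offset was not tested. The simulated trend was built on the same lengths that the offset uses, so removal of a trend with other lengths was not tested. Of genes simulated in both lines 98 of 100 opposite and 7 of 9 in the same direction were found.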

Results

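Bulk RNA-seq gene counts were analysed for 2 epithelial cancer cell lines in which the level of the zinc finger protein ZNF296 (Zfp296 in mouse) was changed in opposite directions. A549 is a human lung cancer line: 3 control libraries were set against 3 libraries from cells that overexpressed ZNF296 after lentiviral delivery. 4T1 is a mouse mammary cancer line: 2 libraries with the non-targeting guide sgNTC were set against 2 libraries in which CRISPR interference, a guide-directed block of transcription, was aimed at Zfp296 with the guide sgZfp296-1. The A549 libraries held 17360074 to 19542690 counts and the 4T1 libraries 30214849 to 33697861. Nothing in the labels says whether the replicates came from separate cultures, so the p-values measure only spread between libraries, which may be technical. The test also pools this spread over genes, with median prior degrees of freedom of 9.47 in A549 and 325 in 4T1. In 4T1 a gene's p-value therefore rests almost wholly on the pooled spread and hardly on that of its own libraries.

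The target gene moved as each library's label states. ZNF296 (ENSG00000170684; GRCh38 chromosome 19, 45071500 to 45076588, minus strand) was at 6.60, 7.0 and 5.08 CPM (counts scaled to library size) in A549 control replicates 1 to 3 and at 211.7, 261.2 and 279.3 CPM in overexpression replicates 1 to 3. The means were 6.23 ± 1.02 and 250.7 ± 35.0 CPM (SD, n = 3 each), a 40.2-fold difference (log2 fold change 5.33, SE 0.13, adjusted p = 3.42e-12). The counts do not separate vector-derived from endogenous transcripts. In 4T1, Zfp296 was at 18.59 and 19.89 CPM in the sgNTC libraries and at 3.80 and 2.32 CPM in the sgZfp296-1 libraries, means of 19.2 ± 0.917 and 3.06 ± 1.05 CPM (SD, n = 2 each). Its log2 fold change was -2.65 (SE 0.17, adjusted p = 5.69e-37), which left residual Zfp296 transcripts in both knockdown libraries.

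**Figure D1:**
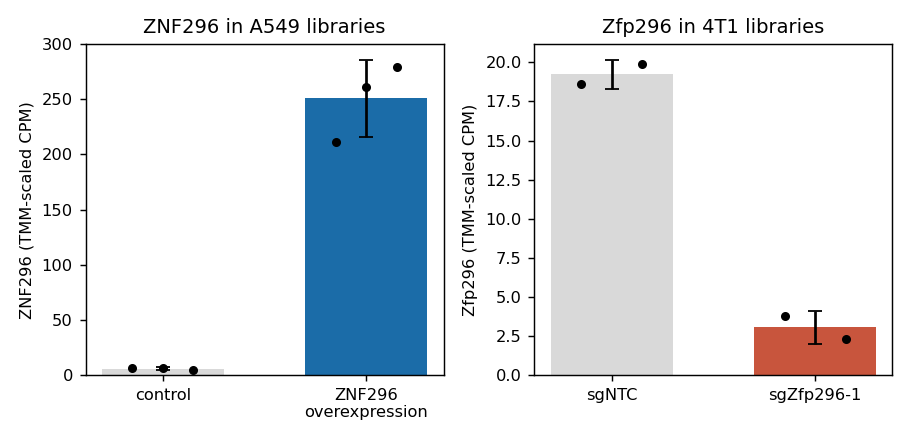
ZNF296 in A549 libraries (left, n = 3 per group) and Zfp296 in 4T1 libraries (right, n = 2 per group), in TMM-scaled CPM. Bars are group means, error bars are SD and points are single libraries. The overexpression libraries lie between 211.7 and 279.3 CPM against 5.08 to 7.0 CPM in controls, and the knockdown libraries lie at 3.80 and 2.32 CPM against 18.59 and 19.89 CPM.

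The A549 comparison asked which transcripts depend on added ZNF296. Interferon-stimulated genes fell as a list, and 28 of 38 members did so singly. The chemokine CCL5, which attracts T cells, was at 592.2 ± 42.0 CPM in control and 16.2 ± 2.04 CPM in overexpressing cells (log2 fold change -5.19, SE 0.10, adjusted p = 4.59e-13), and the related CXCL10 fell too (-5.60). Ribosomal protein genes (57 of 58) and targets of NRF2, the regulator of the oxidative stress response (17 of 25), rose. None of the 3 lists passed with an estimated correlation (adjusted p = 0.0843 for interferon-stimulated genes and 0.418 for the other lists). KRT18, a keratin of simple epithelia, went from 1575 ± 124 to 6791 ± 1128 CPM (log2 fold change 2.11). Of 16031 genes tested, 11253 changed, 5466 higher and 5787 lower, and 3728 of them changed at least 2-fold, 1680 higher and 2048 lower. In 12042 genes (75.12%) the control and overexpression libraries did not overlap, against 10% by chance with 3 libraries in each group.

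Besides ZNF296 itself, the largest increases among well-measured genes were in KRT4, a keratin of stratified mucosa (0.378 ± 0.0756 to 35.2 ± 1.96 CPM, log2 fold change 6.51), and the germ cell alkaline phosphatase ALPG (5.07). They were followed by the eosinophil chemokine CCL26 (4.63), WNT6 (4.50), the R-spondin receptor LGR6 (4.48), the retinal reductase DHRS3 (4.26) and the iron-siderophore binding protein LCN2 (4.14). The largest decreases were in the type III interferon IFNL1, where 578 counts in the control libraries faced 2 in the overexpression libraries (ratio 259, 95% counting interval 71.3 to 2140), and in the chemokine CXCL11 (496 against 2 counts, ratio 222, 61.1 to 1840). LRRC38, an auxiliary subunit of potassium channels, had a ratio of 146 (49.5 to 709, 488 against 3 counts). Lower as well were RSAD2, the antiviral enzyme viperin (log2 fold change -6.74), the hydrogen peroxide-producing oxidase DUOX2 (-5.82), CXCL10 (-5.60), the matrix proteoglycan SPOCK1 (-5.22) and CCL5 (-5.19). Adjusted p lay between 4.59e-13 and 1.20e-08 for all 15 of these genes, and no library of 1 group overlapped the other.

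Interferon-stimulated genes as a list were lower with added ZNF296. Of 38 tested members 28 fell, 3 rose and 7 did not pass, with the same counts adjusted over the list alone, and their median log2 fold change was -1.25. OASL, an antiviral 2'-5' oligoadenylate synthetase-like protein, fell from 332.5 ± 12 to 12 ± 1.01 CPM, and IFIT2 and IFIT3, which bind viral RNA or its sensors, fell too (log2 fold change -5.0 and -4.22), whereas IFI35 rose (1.04). The set test gave an adjusted p of 9.51e-07, and adjusted p = 0.0843 with an estimated correlation. Transcript length and GC content, described for all genes further on, moved with the groups too, and with an offset for that trend 32 members fell and 3 rose (median -1.02, adjusted p = 2.59e-11, and 0.0308 with an estimated correlation).

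Genes of interferon receptor signalling, including the interferons themselves, were lower as a list: 11 of 21 tested members fell and 2 rose, also when adjusted over the list alone (median -0.41, adjusted p = 0.0363, and adjusted p = 0.418 with an estimated correlation). IFNL1 fell, and so did the near-identical genes IFNL3 (290 against 1 count, ratio 260, 95% counting interval 46.2 to 10300) and IFNL2 (286 counts against 0, at least 85.3-fold lower against a floor of 3 counts over the group). Reads of IFNL2 and IFNL3 can be shared, so their separate values are uncertain. The tyrosine phosphatase PTPN6 rose (log2 fold change 0.59), but was at 0.05 (adjusted p = 0.538) with the length and GC offset. The list's call ended with that offset (adjusted p = 0.0794) and without control replicate 1 (0.0583), control replicate 3 (0.0588) or overexpression replicate 3 (0.0661).

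Sensors of foreign nucleic acid went both ways. Of 20 tested members 12 fell and 5 rose (the same adjusted over the list alone), and the list did not pass (median -0.56, adjusted p = 0.136). The RNA helicase sensors RIGI (71.5 ± 3.3 to 9.82 ± 0.750 CPM, log2 fold change -2.86) and IFIH1 (-3.21) and the DNA sensor IFI16 (-2.13) fell, while the transcription factor IRF3 rose (1.06, and 0.29 with the offset). Chemokines likewise split, with 7 of 13 lower and 4 higher in both adjustments (median -0.30, adjusted p = 0.222): CCL5, CXCL10 and the neutrophil chemokine CXCL5 (939.2 ± 32.7 to 247.1 ± 36.7 CPM) fell and CCL26 rose. Among secreted cytokines and growth factors 8 of 21 fell and 5 rose in both adjustments (adjusted p = 0.575), with IL6 (-3.94), the EGF receptor ligand EREG (-2.04) and the death ligand TNFSF10 (-1.93) lower and the stress cytokine GDF15 higher (1.13, and 0.18 with the offset).

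Antigen presentation genes did not move as a block. In the MHC class I list 11 of 21 members rose and 7 fell in both adjustments (median 0.29, adjusted p = 0.222). The proteasome activator subunits PSME2 (1.13, and 0.40 with the offset) and PSME1 (0.93, 0.29) and the chaperone CALR (0.80, 0.34) rose, and the chaperone CANX fell (-0.71, -0.23). Of 5 tested MHC class II genes, the peptide exchange subunits HLA-DMA (1.57) and HLA-DMB (0.67) rose and CD74, the class II invariant chain, fell (-1.40), in both adjustments (adjusted p = 0.759). HLA-DMB did not pass with the offset (0.13, adjusted p = 0.487), and CD74, at 0.619 ± 0.132 CPM in control, did not pass without control replicate 2 or overexpression replicate 1 (adjusted p = 0.0608 in each) or in DESeq2 (0.101). Among immune checkpoint molecules and ligands of killer-cell receptors 14 of 22 fell and 4 rose in both adjustments (median -0.63, adjusted p = 0.0781, 0.0274 without a filter on low counts, 0.013 with the offset, and with the offset adjusted p = 0.233 with an estimated correlation). NT5E, the ectonucleotidase CD73, fell from 79.5 ± 2.61 to 20.5 ± 0.444 CPM, the B7 family member CD276 fell by 1.06 on the log2 scale, and RAET1L, a ligand of the NKG2D receptor, had a ratio of 54.6 (18.4 to 267, 183 against 3 counts), while the checkpoint VSIR rose (log2 fold change 2.68).

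Of NF-kB target genes 11 of 22 fell and 4 rose in both adjustments, and the list did not pass (median -0.24, adjusted p = 0.108). With the offset it passed (0.00069), but not with an estimated correlation as well (adjusted p = 0.233). Without a filter on low counts it passed too (0.0252). The prostaglandin synthase PTGS2 (-2.17), the apoptosis inhibitor BIRC3 (-1.80) and the mitochondrial superoxide dismutase SOD2 (-1.38) fell and LCN2 rose (4.14). Immediate-early and heat shock genes had 9 members lower and 6 higher of 19 in both adjustments (median -0.10, adjusted p = 0.759, 0.013 with the offset, and with the offset adjusted p = 0.233 with an estimated correlation). Both JUNB (-1.31) and FOS (-1.17) fell. The small heat shock protein HSPB1 rose (1.04) and the chaperone HSPH1 fell (-0.58), but with the offset these were -0.05 (adjusted p = 0.311) and 0.06 (0.266).

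Epithelial genes had 12 of 20 members higher and 8 lower (median 0.60, adjusted p = 0.222), and mesenchymal and extracellular matrix genes 16 of 29 lower and 9 higher (median -0.38, adjusted p = 0.222), with the same counts adjusted over each list alone. KRT18, the tight junction protein TJP3 (2.34) and the epithelial transcription factor ELF3 (1.11) rose, while the desmosomal protein DSP fell from 226.6 ± 17.2 to 50.8 ± 6.72 CPM. The fibrillar collagen gene COL5A1 (-2.2), the mesenchymal repressor ZEB2 (-2.69) and the matrix protein SPARC (-1.41) fell, and the gelatinase MMP2 rose (2.59). WNT target genes rose in 7 and fell in 4 of 13 cases in both adjustments (adjusted p = 0.222): LGR6, WNT7B (1.28) and RNF43 (0.88) rose and TNFRSF19 fell (-1.42). RNF43 is uncertain because 73.9% of its exon bases lie in another annotated gene. Pluripotency genes fell in 8 and rose in 1 of 11 cases in both adjustments (adjusted p = 0.0978, 0.0264 with the offset, and with the offset adjusted p = 0.262 with an estimated correlation), with MYCN (-2.85), KLF4 (-1.39) and KLF5 (-0.86) lower. POU5F1 rose (0.64) but did not pass without control replicate 3 (adjusted p = 0.0502) or with the offset (0.0739).

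Markers of lung rose in 4 and fell in 3 of 8 cases in both adjustments (adjusted p = 0.759): the mucin MUC5AC (-1.20) and MUC5B (-0.57) fell, and CAV1 (0.52) and FOXA1 (0.99) rose. Few markers of other cell types reached the level for testing. Among 6 leukocyte markers CD14 (1.76) and CORO1A (2.27) rose and LAPTM5 fell (-3.25), and among 5 fibroblast and endothelial markers THY1 rose (3.20) and LUM (-3.72) and PDGFRA (-1.40) fell, with the same counts adjusted over each list alone (list adjusted p = 0.576 and 0.759). PDGFRA was at 0.775 ± 0.216 CPM in control and did not pass without control replicate 1 (adjusted p = 0.0606), without overexpression replicate 2 (0.0701), in DESeq2 (0.0736) or with the offset (0.159).

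Ribosomal protein genes rose together, 57 of 58 in both adjustments (median log2 fold change 0.97, adjusted p = 6.01e-18, and adjusted p = 0.418 with an estimated correlation). RPL28 went from 543.4 ± 13.3 to 1567 ± 263 CPM (1.53), and RPL13A (1.25) and RPL38 (1.24) behaved alike. The mitochondrially encoded genes were higher as a list, 11 of 13 rising and MT-ND4L falling in both adjustments (median 0.71, adjusted p = 0.00225, and adjusted p = 0.418 with an estimated correlation), with MT-ND3 at 1.12 and MT-ND1 at 0.93. MT-ND6 (1.34) is encoded on the strand opposite to its neighbours and is uncertain in unstranded counts, and MT-ND4L (-1.07) overlaps MT-ND4. NRF2 target genes were higher, 17 of 25 rising and 5 falling in both adjustments (median 0.63, adjusted p = 0.0133, and adjusted p = 0.418 with an estimated correlation). The glutathione peroxidase GPX2 (299.2 ± 21.1 to 920.9 ± 122 CPM) and the oxidative stress-induced growth inhibitor OSGIN1 (1.69) rose, while the cystine transporter SLC7A11 (-1.23, and -0.22 with the offset) and the export pump ABCC2 (-0.92, -0.42) fell.

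Several technical measures moved with these groups. The mitochondrial share of counts was 8.37, 9.06 and 8.75% in the control libraries and 11.64, 11.69 and 11.65% in the overexpression libraries, and the 10 most abundant genes took 9.01 to 9.76% and 12.88 to 13.18%. The fold changes of 13051 genes followed transcript length (Spearman rho across genes -0.54) and GC content (0.547), the shortest 10% of genes having a median log2 fold change of 0.722 and the longest 10% -0.721. Length and GC content together accounted for 33.9% of the variance of the fold changes. Each overexpression library had a rho of -0.524 to -0.554 with length against the control mean, and the control libraries had 0.312, -0.281 and -0.0798. With an offset per library for this trend 9707 genes changed, 4322 higher and 5385 lower, of which 7831 were among the calls without it, and 803 genes were called in opposite directions by the fits with and without the offset. Changes of at least 2-fold then numbered 2321 (856 higher, 1465 lower). The offset brought the median of the ribosomal protein genes to 0.46 (51 rose, adjusted p = 1.20e-16), of the mitochondrially encoded genes to 0.29 (10 rose, 0.00234) and of the NRF2 target genes to 0.33 (19 rose, 3 fell, 1.14e-05), and ZNF296 to 4.43. With an estimated correlation these 3 lists had adjusted p = 0.262, 0.262 and 0.233. Whether the control and overexpression libraries were prepared and sequenced together is not given in the sources used here, so a difference in preparation cannot be separated from the groups.

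The offset also moved the medians of lists that did not pass. The nucleic acid sensors went to -0.0925 (6 rose, 9 fell), MHC class I genes to 0.0373 (9 rose, 7 fell), epithelial genes to 0.202 (9 rose, 7 fell) and chromatin repressors to 0.0123. The MHC class II median went to 0.319, that of chemokines to -0.62, of cytokines and growth factors to -0.374, of NF-kB target genes to -0.588 (3 rose, 15 fell), of hypoxia and glycolysis genes to -0.151 and of immediate-early and heat shock genes to -0.198 (10 fell). Signs turned for lung markers (-0.101, 2 rose and 4 fell), cholesterol synthesis genes (-0.247, 7 rose and 13 fell), the integrated stress and unfolded protein response (-0.327, 3 rose and 16 fell) and proliferation genes (-0.0238, 7 rose and 13 fell). The test of fibroblast and endothelial markers pointed higher with the offset and lower without it.

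The other A549 lists did not pass. The p53 target genes rose in 15 and fell in 3 of 23 cases in both adjustments (median 0.34, adjusted p = 0.0510, 0.00394 with the offset, and adjusted p = 0.418 and 0.233 with an estimated correlation, without and with the offset), with the mitochondrial reductase FDXR (2.03), the cell death effector BAX (1.69) and the DNA damage-binding protein DDB2 (0.92) higher and the death receptor TNFRSF10B lower (-0.60). This list passed without control replicate 1 (adjusted p = 0.0371) or overexpression replicate 1 (0.0198), with DESeq2's size factors (0.0489) and without a filter on low counts (0.00358), settings in which an estimated correlation was not tried. The integrated stress and unfolded protein response list had 9 members higher and 11 lower of 27 in both adjustments (adjusted p = 0.759, 0.00803 with the offset, and with the offset adjusted p = 0.233 with an estimated correlation). Its median was 0.03 while its mean was -0.13 and its test pointed lower. The endoplasmic reticulum genes SEL1L (-1.62), DNAJC3 (-1.29) and EDEM1 (-1.14) fell and PHGDH, of serine synthesis, rose (1.17). Cholesterol synthesis genes rose in 9 and fell in 12 of 25 cases, 10 and 12 adjusted over the list alone (median 0.03, mean -0.12, test lower, adjusted p = 0.759), with STARD4 (-1.32) lower and NSDHL higher (0.62).

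Hypoxia and glycolysis genes rose in 10 and fell in 9 of 24 cases in both adjustments (median -0.00, mean -0.03, test higher, adjusted p = 0.759): ENO2 (0.98) and ADM (1.06) rose and hexokinase HK2 (-1.70) and the glucose transporter SLC2A1 (-0.59) fell. Chromatin repressors rose in 13 and fell in 11 of 35 cases in both adjustments (adjusted p = 0.738), the Polycomb subunit SUZ12 (-1.04) and the remodeller ATRX (-1.60, and -0.63 with the offset) falling and the DNA methyltransferase DNMT3B (1.00) and the KRAB zinc finger corepressor TRIM28 (0.87, 0.32) rising. Proliferation genes rose in 14 and fell in 13 of 32 cases in both adjustments (median 0.03, adjusted p = 0.759), with CCND1 (-0.73) and MKI67 (-0.72) lower and MCM5 (0.73) and CDT1 (0.99), both of DNA replication licensing, higher. In total 5 of 26 lists passed, 0 with an estimated correlation. A rotation test (fry) of whether a list's genes move on balance one way, without comparing them to other genes, passed 20. Its mixed form, which tests for change in either direction, passed 26.

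The 4T1 comparison asked which transcripts depend on endogenous Zfp296. After knockdown, inflammatory and matrix genes rose while epithelial, cholesterol synthesis and ribosomal protein genes fell modestly, each as a list, though with an estimated correlation none passed (adjusted p = 0.210 or more). The neutrophil chemokine gene Cxcl5 went from 42.9 ± 0.649 to 357.3 ± 0.488 CPM (SD, n = 2, log2 fold change 3.06, SE 0.05, adjusted p = 4.94e-189), complement C3 rose by 3.03 on the log2 scale, and the intermediate filament gene Vim went from 1186 ± 4.00 to 2680 ± 26.9 CPM (1.18). Cdh1, which encodes E-cadherin, fell from 778.1 ± 2.2 to 457.4 ± 0.359 CPM (-0.77). Of 12364 genes tested 4613 changed, 2321 higher and 2292 lower. Only 529 of them changed at least 2-fold, 471 higher and 58 lower. The libraries of the groups did not overlap for 8128 genes (65.74%, against 33.3% by chance with 2 libraries in each group).

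Lcn2 had the largest increase among well-measured genes (0.0952 ± 0.0496 to 12.5 ± 0.416 CPM, log2 fold change 7.0). Among those that followed were the protease inhibitors Serpine2 (4.43) and Serpina3h (3.73), Glipr2 (3.57), Pdgfrl (3.49), the collagen VI gene Col6a1 (1.75 ± 0.475 to 18.8 ± 1.28 CPM, 3.43) and the TGF-beta coreceptor Tgfbr3 (3.41). Serpina3h has close relatives in its gene cluster, and its counts are uncertain. Next to Zfp296 the largest decreases were in Misp3 (5.73 ± 0.0939 to 0.795 ± 0.0603 CPM, -2.84), the Snail family gene Snai3 (-2.64), Wnt10a (-2.13), the transcription factor Sox15 (-1.59), the long non-coding RNA Lncenc1 (95.6 ± 1.57 to 32.8 ± 3.62 CPM, -1.54), Serpinb2 (-1.45) and S100a14 (-1.38). Adjusted p was between 2.45e-79 and 6.33e-10 for these genes, and the 2 libraries of each group did not overlap those of the other.

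Chemokines were higher as a list, with 9 of 13 tested members rising and none falling, and 11 rising adjusted over the list alone (median 1.54, adjusted p = 1.96e-08, and adjusted p = 0.222 with an estimated correlation). Besides Cxcl5 these included the neutrophil chemokine Cxcl1 (29.1 ± 2.85 to 142.9 ± 3.55 CPM, 2.29), the membrane-bound Cx3cl1 (1.54) and the monocyte chemokine Ccl2 (1.56). NF-kB target genes rose in 12 and fell in 2 of 23 cases in both adjustments (median 0.42, adjusted p = 7.45e-07, and adjusted p = 0.210 with an estimated correlation), C3, Lcn2 and Tnfaip2 (0.91) rising and Ptgs2 falling (-0.13). Secreted cytokines and growth factors rose in 8 and fell in 4 of 21 cases, and in 11 and 4 adjusted over the list alone (median 0.59, adjusted p = 0.0233, adjusted p = 0.330 with an estimated correlation, and 0.0508 without a filter on low counts). The granulocyte factor Csf3 (48.9 ± 3.94 to 155.5 ± 0.786 CPM, 1.67), Il1a (1.13) and the macrophage factor Csf1 (0.61) rose, and Tslp fell (-0.81).

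MHC class I genes were slightly higher as a list, 9 of 25 rising and 2 falling in both adjustments (median 0.17, adjusted p = 0.0171, and adjusted p = 0.330 with an estimated correlation). Nlrc5, the transactivator of class I genes, went from 29.2 ± 1.02 to 56.1 ± 4.03 CPM (0.94), B2m rose by 0.24 on the log2 scale, and H2-Q4 rose (0.62), though reads of the H2-Q genes can be shared. Canx fell (-0.13) and did not pass without knockdown replicate 1 (adjusted p = 0.0561). Of 3 tested class II genes, too few for a list test, Cd74 rose (1.60) and Ifi30 fell (-0.20), and 3 passed adjusted over the list alone, 2 higher and 1 lower. Cd74 did not pass without sgNTC replicate 2 (adjusted p = 0.109), knockdown replicate 1 (0.0855) or knockdown replicate 2 (0.0939). Ifi30 did not pass when any of the 4 libraries was left out (adjusted p between 0.0668 and 0.277), nor in DESeq2 (0.158), without a filter (0.0524) or with the length and GC offset (0.387).

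Interferon-stimulated genes did not pass as a list in 4T1. Of 46 tested members 14 rose and 7 fell, 16 and 7 adjusted over the list alone (median 0.08, adjusted p = 0.156). Parp14 (0.45), Helz2 (0.37) and Herc6 (0.68) rose and the oligoadenylate synthetase Oas3 fell (-0.32). A length and GC value, which the offset needs, was found for 80.4% of the members, and the others stayed uncorrected. The list passed, higher, without knockdown replicate 1 (adjusted p = 0.0302) and with the offset (0.0179, 18 rising and 5 falling), but not with the offset and an estimated correlation (adjusted p = 0.507). Interferon receptor signalling genes rose in 6 and fell in 1 of 17 cases, 6 and 2 adjusted over the list alone (median 0.16, adjusted p = 0.0506, 0.0403 without knockdown replicate 1, 0.0334 with the offset, and with the offset adjusted p = 0.368 with an estimated correlation). The kinase Jak2 (0.52) and the receptor subunit Ifnar2 (0.64) rose. Ifnar1 rose (0.32) but did not pass without knockdown replicate 1 (0.0792). Nucleic acid sensors rose in 8 and fell in 5 of 21 cases in both adjustments (adjusted p = 0.481), with Zbp1 (0.61) and Dhx58 (0.39) higher and Rnaseh2c lower (-0.39). Checkpoint and killer-cell ligand genes rose in 4 and fell in 3 of 13 cases in both adjustments (adjusted p = 0.18), among them Nt5e (61.1 ± 3.27 to 114.6 ± 3.12 CPM, 0.91), Cd47 (0.58) and Ulbp1 (0.67) higher and Lgals3 lower (-0.50).

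Mesenchymal and extracellular matrix genes were higher, 12 of 21 rising and 4 falling in both adjustments (median 0.54, adjusted p = 3.07e-06, and adjusted p = 0.330 with an estimated correlation). Vim, the fibronectin gene Fn1 (2125 ± 77.1 to 3225 ± 77.2 CPM, 0.60) and Col5a1 (2.22) rose and thrombospondin Thbs1 fell (1430 ± 25.9 to 615.0 ± 15.1 CPM, -1.22). Epithelial genes were lower, 19 of 26 falling and 2 rising, 19 and 4 adjusted over the list alone (median -0.34, adjusted p = 6.05e-12, and adjusted p = 0.210 with an estimated correlation), with Cdh1, the claudin gene Cldn4 (-0.67) and Krt7 (-0.51) lower and Tjp3 higher (1.61). Markers of mammary tissue rose in 3 and fell in 1 of 8 cases in both adjustments (adjusted p = 0.582): the basal keratin gene Krt14 fell (-0.53) and Plet1 rose (0.62). Ltf, with 0 counts in sgNTC and 21 in knockdown libraries (at least 7.27-fold higher against a floor of 3 counts over the group), did not pass without sgNTC replicate 1 (adjusted p = 0.0632) or 2 (0.0683). Gata3 rose (0.18) but did not pass without sgNTC replicate 1 (0.0728) or knockdown replicate 2 (0.0599).

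Markers of other cell types were few. Of 4 leukocyte markers tested Cd14 rose (0.45) and Csf1r fell (-0.65), and of 3 fibroblast and endothelial markers Pdgfra rose (2.44 ± 0.369 to 9.78 ± 1.02 CPM, 2.0) and Postn fell (-0.71), with the same counts adjusted over each list alone. Both lists were too short for a test. Csf1r did not pass without sgNTC replicate 2 (adjusted p = 0.124), without knockdown replicate 1 (0.30) or in DESeq2 (0.113). The call of Cd14 ended without sgNTC replicate 2 (0.148), knockdown replicate 1 (0.10) or knockdown replicate 2 (0.0811) and in DESeq2 (0.0936), and that of Postn without knockdown replicate 2 (0.0866).

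Cholesterol synthesis genes fell in 22 of 24 cases and none rose, and 23 fell and 1 rose adjusted over the list alone (median -0.41, adjusted p = 3.93e-15, and adjusted p = 0.210 with an estimated correlation). Fdps (278.5 ± 5.25 to 189.5 ± 15.6 CPM, -0.56), the demethylase Cyp51 (-0.52) and the sterol sensor gene Insig1 (-0.49) all fell. Ribosomal protein genes fell in 41 and rose in 1 of 57 cases in both adjustments (median -0.20, adjusted p = 4.00e-18, adjusted p = 0.414 with an estimated correlation, and 0.0682 in the rotation test). Rpl7 (-0.31), Rps12 (-0.31) and Rpl10 (-0.28) fell. Rps29 rose (0.22) but did not pass without sgNTC replicate 1 (0.392) or knockdown replicate 2 (0.469), in DESeq2 (0.171) or with the offset (0.175). Hypoxia and glycolysis genes were higher, 13 of 24 rising and 3 falling, 13 and 4 adjusted over the list alone (median 0.22, adjusted p = 0.00347, and adjusted p = 0.453 with an estimated correlation). The oxygen-sensing hydroxylase Egln3 (19.7 ± 1.67 to 59.8 ± 1.29 CPM, 1.61), Bnip3 (1.00) and Tpi1 (0.27) rose. Adm fell (-0.88) but did not pass without knockdown replicate 2 (0.0567).

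The 10 most abundant genes took 4.81 and 4.84% of counts in the sgNTC libraries and 4.52 and 4.54% in the knockdown libraries, and the ribosomal RNA precursor Rn45s 0.33 and 0.34% against 0.29 and 0.24%. The fold changes of 4T1 genes followed transcript length with a Spearman rho of 0.284 across 9604 genes and GC content with 0.00311, both taken from the human gene of the same symbol, and these accounted for 4.55% of the variance. With the offset 4326 genes changed, 3711 of them also called without it, and 515 at least 2-fold. The median of the ribosomal protein genes was then -0.10 and that of the mesenchymal genes 0.40. Signs turned for proliferation genes (0.045, 12 rose and 5 fell) and chromatin repressors (-0.0396, 6 rose and 10 fell), and the medians of WNT target (0.0408), pluripotency (0.0573), p53 target (-0.0466), stress response (0.0189) and interferon receptor signalling genes (0.239) moved by over 1.5 times. For the MHC class I and NRF2 lists this check is void, because only 60% and 77.3% of their members had a value.

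Other 4T1 lists did not pass. Proliferation genes rose in 5 and fell in 9 of 32 cases in both adjustments (median -0.03, mean 0.02, test lower, adjusted p = 0.964), with Ccnd1 (0.39), Mki67 (0.28) and Foxm1 (0.30) higher and Mcm3 lower (-0.23). The p53 target genes rose in 4 and fell in 5 of 20 cases, 4 and 6 adjusted over the list alone (median -0.03, mean 0.11, test lower, adjusted p = 0.527), Cdkn1a rising (7.64 ± 0.538 to 15.8 ± 0.220 CPM, 1.05) and Plk2 (-0.42), Ccng1 (-0.46) and Aen (-0.35) falling. Integrated stress and unfolded protein response genes rose in 6 and fell in 10 of 27 cases in both adjustments (median 0.01, mean 0.00, test lower, adjusted p = 0.18). Asns (-0.60), Psat1 (-0.36) and Shmt2 (-0.35), all of amino acid synthesis, fell and Cebpb rose (0.55). NRF2 target genes rose in 5 and fell in 7 of 22 cases, 6 and 8 adjusted over the list alone (median -0.05, mean 0.18, test lower, adjusted p = 0.760), with Ugdh (0.79) and Akr1b8 (0.54) higher and G6pdx (-0.31) and Ftl1 (-0.18) lower.

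Immediate-early and heat shock genes rose in 5 and fell in 7 of 21 cases in both adjustments (median -0.06, mean 0.10, test lower, adjusted p = 0.18, and 0.0413 without sgNTC replicate 1). The chaperones Hspa8 (-0.34), Hspd1 (-0.35) and Hsp90aa1 (-0.17) fell and Jun rose (0.27). Chromatin repressors rose in 9 and fell in 9 of 35 cases in both adjustments (median 0.02, mean -0.02, test higher, adjusted p = 0.964). Chd4 rose (0.22), and Mbd2 (-0.35) and Mbd3 (-0.23) fell. WNT target genes rose in 4 and fell in 1 of 12 cases, 5 and 1 adjusted over the list alone (adjusted p = 0.163). Apcdd1 (1.14), Lgr6 (0.95) and Tnfrsf19 (2.49) were higher and Wnt7a lower (-0.30). Tnfrsf19 had 4 and 18 counts in sgNTC and 60 and 59 in knockdown libraries, so its fold is uncertain. Of 5 pluripotency genes Myc fell (561.4 ± 20.3 to 400.3 ± 4.93 CPM, -0.49) and Klf4 rose (0.78), in both adjustments (median 0.03, mean 0.09, test lower, adjusted p = 0.786). In total 9 of 22 lists passed, 0 with an estimated correlation, and the rotation test passed 12.

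**Figure D2:**
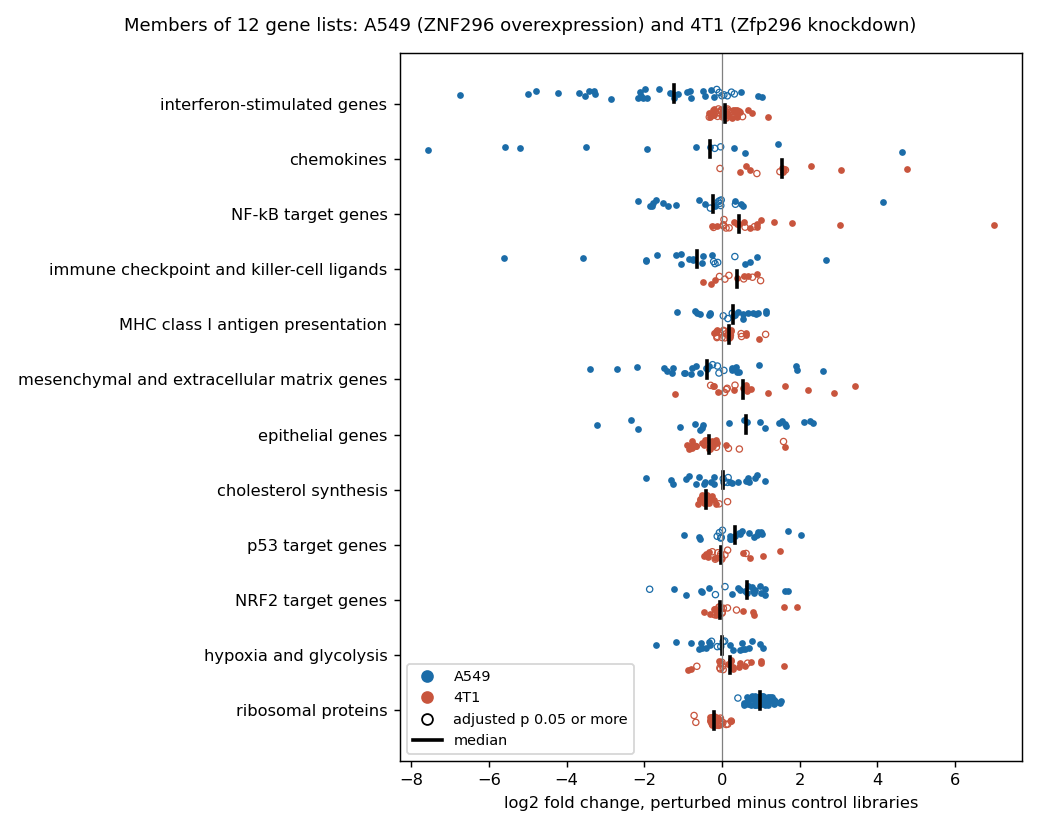
Log2 fold change (perturbed minus control libraries) of each tested member of 12 gene lists in A549 (ZNF296 overexpression, n = 3 per group) and 4T1 (Zfp296 knockdown, n = 2 per group). Points are genes, open points have an adjusted p of 0.05 or more and vertical ticks are medians. Interferon-stimulated genes have a median of -1.25 in A549 and 0.08 in 4T1, chemokines -0.30 and 1.54, and ribosomal proteins 0.97 and -0.20.

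Setting the lines side by side asked whether genes that moved with added ZNF296 moved the other way with less of it. Of 10025 genes paired by symbol, 3227 were called in both lines, 1997 of them (61.88%) in opposite and 1230 in the same direction. Higher in A549 and lower in 4T1 were 904 genes against 733.1 for independent lists (odds ratio 1.56, Fisher's exact p = 3.06e-18), and lower in A549 and higher in 4T1 were 1093 against 823.5 (1.99, p = 3.63e-42). Both-higher genes numbered 496 against 700.6 (odds ratio 0.547, Fisher's exact p = 6.65e-28) and both-lower genes 734 against 861.7 (0.722, p = 1.45e-10). Genes are not independent replicates, so these p-values describe overlap across genes and not between samples. Across all paired genes the fold changes had a Pearson r of -0.0812 and a Spearman rho of -0.155. With length and GC offsets in both fits 1454 genes were opposite and 1199 the same (54.81%), r was -0.0462 and rho -0.0659. By Fisher's exact test the odds ratios of the opposite calls were then 1.39 (p = 6.74e-10) and 1.38 (p = 1.88e-09), that of both-higher genes 0.88 (p = 0.0293), and both-lower genes, 714 against 718.9, no longer passed (0.987, p = 0.815). Without sgNTC replicate 2 the r was -0.0368.

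The opposite calls with the largest changes were in PLXNA4, a semaphorin receptor (log2 fold change -4.28 in A549 and 4.02 in 4T1), the semaphorin gene SEMA6D (60 counts against 1 in A549, ratio 53.7, 95% counting interval 9.28 to 2160, and 3.12 in 4T1) and ANO4 (-3.57 in A549, and 41 against 2 counts in 4T1, ratio 21.3, 5.53 to 182). ANO4 was at 0.117 ± 0.202 CPM in the A549 overexpression libraries, an SD above the mean, so its fold there is uncertain. The metabolic coactivator gene PPARGC1A fell by 2.81 on the log2 scale in A549. In 4T1 it was at 0 counts in sgNTC and 37 in knockdown libraries (at least 12.8-fold higher). Similar opposition was found for the deiodinase DIO2 (-2.50 and 2.59), the pseudokinase TRIB2 (-2.95 and 2.45) and the cytokine receptor LIFR (-2.26 and 3.36). CCN3 (-3.37 and 2.69) was also called, but its 4T1 call ended without sgNTC replicate 2 (adjusted p = 0.143), without knockdown replicate 2 (0.0668) and in DESeq2 (0.405).

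Against 61.88% over all genes called in both lines, ribosomal proteins were opposite in 40 of the 41 members called in both, chromatin repressors in 12 of 16, stress response genes in 9 of 12, interferon-stimulated genes in 11 of 15, chemokines in 5 of 7, epithelial genes in 11 of 17 and cholesterol synthesis genes in 9 of 17. Fewer opposite than shared directions were found for NF-kB target genes (3 of 8), mesenchymal and matrix genes (6 of 13) and hypoxia and glycolysis genes (6 of 14). No list's share was tested against that over all genes. These shares, and the single-gene values that follow, are without the length and GC offset. The fold changes followed transcript length in opposite directions (rho -0.54 in A549 and 0.284 in 4T1), so opposition cannot be told apart from that trend here. With the offset the share over all genes was 54.81%. Ribosomal protein genes then rose in 51 cases in A549, and in 4T1 29 fell and 2 rose. Single genes named in either line went both ways. CXCL5 (-1.93 and 3.06), CX3CL1 (-3.50 and 1.54), CCL5 (-5.19 and 0.47), CXCL10 (-5.60 and 0.71), NT5E (-1.95 and 0.91), NLRC5 (-1.15 and 0.94), COL5A1 (-2.2 and 2.22), ZEB2 (-2.69 and 1.63) and JAK2 (-1.81 and 0.52) were lower in A549 and higher in 4T1. KRT18 (2.11 and -0.32), KRT7 (0.99 and -0.51), CDH1 (0.56 and -0.77) and DNMT3B (1.00 and -0.80) were higher in A549 and lower in 4T1. Among the named interferon-stimulated genes paired by symbol, those with the steepest A549 decreases had small 4T1 values. IFIT2 was at 0.06 (adjusted p = 0.703), RSAD2 fell slightly (-0.22) and IFIT3 rose slightly (0.38). Direction was shared by LCN2 (4.14 and 7.0), CCL2 (1.45 and 1.56), TJP3 (2.34 and 1.61) and LGR6 (4.48 and 0.95).

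**Figure D3:**
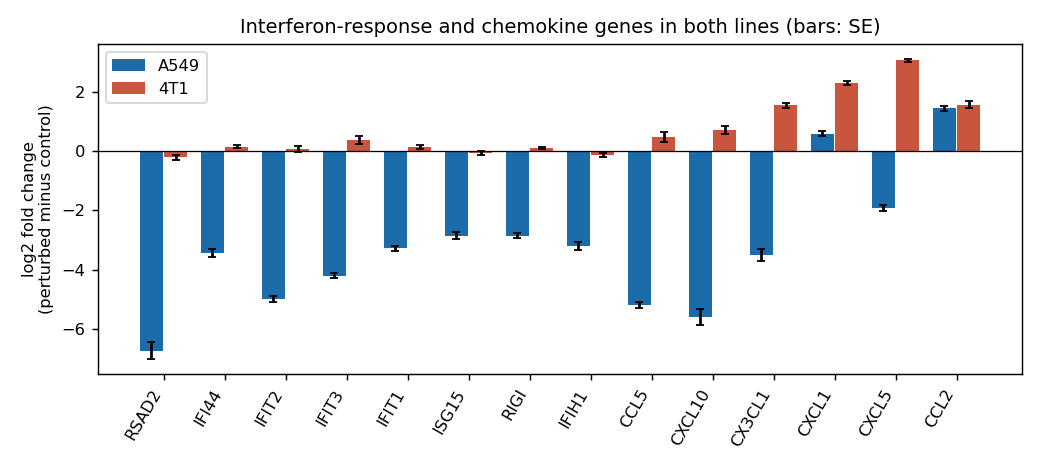
Log2 fold change (perturbed minus control libraries) of interferon-response and chemokine genes in A549 (ZNF296 overexpression) and in 4T1 (Zfp296 knockdown). Bars are fitted values and error bars are SE. RSAD2 is at -6.74 and -0.22, CCL5 at -5.19 and 0.47, and CXCL5 at -1.93 and 3.06, while CCL2 is above 0 in both lines.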

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

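The length and GC offset was added after the data were seen; the other alternatives were set beforehand. Requiring a 2-fold change left 3728 genes in A549 (1680 higher, 2048 lower) and 529 in 4T1 (471 higher, 58 lower). A549 lists called numbered 8 without a filter, 0 with an estimated correlation, 20 by rotation test and 10 with the offset, against 5. With the offset and an estimated correlation 1 passed, the others at 0.233 or more. The 4T1 lists numbered 0 with an estimated correlation against 9. For these shifts the cause was not tested, but the estimated form also has fewer degrees of freedom. Calls were lost even where the estimate lay below the preset 0.01 (NF-kB targets in 4T1, -0.041, and interferon-stimulated genes in A549, -0.00331). The cross-line correlation of -0.0812 was -0.0437 in DESeq2, -0.155 as Spearman, -0.0462 with offsets and -0.0838 (without sgZfp296-1 replicate 2) to -0.0368 (without sgNTC replicate 2) with each library left out. With the offset HSPB1 (-0.053, adjusted p = 0.311) and HSPH1 (0.064, 0.266) lost their A549 calls and changed sign. Counts of changed genes stayed within 1.5-fold otherwise: 10573 to 11514 in A549 and 3460 to 4128 in 4T1 with each library left out, and 3360 for DESeq2 in 4T1. Of single named genes under the alternatives set beforehand 1288 values in A549 kept their direction and side of the threshold and 7 lost the call, as did 984 and 35 in 4T1; with the offset 112 kept and 4 lost theirs in A549 and 109 and 5 in 4T1. For lists these gave 280 kept, 22 gained and 8 lost calls in A549 and 202, 7 and 11 in 4T1, and the offset 19, 6 and 1 in A549 and 20 kept and 2 gained in 4T1, where the check is void for the MHC class I and NRF2 lists among the 20, too few of whose members had a length and GC value. With the replicate number as a block 10803 genes changed in A549 and 4563 in 4T1, and the p53 list was added (adjusted p = 0.0459); it changed no other list's call. Same-numbered libraries had correlations of deviations of -0.0923, 0.00693 and -0.0261 in A549, where differently numbered ones had -0.0579 to 0.0819. No sign of pairing by number was seen there, which does not exclude it. In 4T1 the value was 0.0276, but 2 libraries per group give only 1 value up to its sign, so pairing could not be judged. Depth limits low genes most: IFNL2, IFNL3 and Ltf rest on 0 or 1 count in 1 group.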

Other observations

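Tests of gene families, of fibroblast transcripts and of whether interferon-stimulated genes move against ZNF296 in both lines were chosen only after the result was seen, as was the length and GC offset, while the list tests themselves were set beforehand. In each line 17 families matched by symbol were tested, and with an estimated correlation no family passed. In 4T1 after Zfp296 knockdown semaphorins and plexins, guidance cues and their receptors, rose in 12 and fell in 1 of 20 cases (adjusted p = 2.72e-05, 0.00111 with the offset, and adjusted p = 0.143 with an estimated correlation), with Plxna4 at a log2 fold change of 4.02, Sema6d at 3.12 and Plxnd1 at 1.73. Collagens rose in 10 and fell in 3 of 17 cases (3.42e-05, 0.00196 with the offset, and adjusted p = 0.143 with an estimated correlation), among them Col6a1 (3.43), Col5a1 (2.22) and Col18a1 (1.03), with 4 of the 17 also in the fixed lists. Metalloproteinases of the MMP, ADAM and ADAMTS families rose in 17 and fell in 3 of 29 cases (3.42e-05, 0.000315 with the offset, and adjusted p = 0.143 with an estimated correlation), with the stromelysin gene Mmp3 (3.12) and the collagenase gene Mmp13 (2.78) higher and Adamts1 lower (-1.03). Claudins went the other way, 4 of 9 falling and 1 rising (0.0107, 0.0265 with the offset, and adjusted p = 0.332 with an estimated correlation). Of these 9 claudins, 4 also stand in the fixed lists. Protocadherins rose in 8 and fell in 1 of 18 cases (0.0217) and serpins rose in 7 and fell in 3 of 17 (0.0278), each with adjusted p = 0.266 with an estimated correlation, and too few of their members had a length and GC value for the offset. The call of integrin subunits (8 of 16 rose and 4 fell, 0.039, and adjusted p = 0.526 with an estimated correlation) ended with the offset (0.164).

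Translation initiation factors fell in 33 and rose in 1 of 42 cases in 4T1 (adjusted p = 2.80e-13, 1.39e-11 with the offset, and adjusted p = 0.143 with an estimated correlation), Eif5a at -0.32 and Eif4a1 at -0.29. Mitochondrial ribosomal proteins fell in 47 and rose in 1 of 78 cases (1.63e-09, 0.000315 with the offset, and adjusted p = 0.143 with an estimated correlation), with Mrpl12 at -0.51. Keratins, of which 6 of 11 in 4T1 and 4 of 17 in A549 also stand in fixed lists, fell in 6 cases in 4T1 (7.05e-05, 0.00043 with the offset, and adjusted p = 0.246 with an estimated correlation). In A549 they rose in 12 and fell in 1 (0.000641, 0.00954 with the offset, and adjusted p = 0.389 with an estimated correlation), KRT8 (1.62) rising and KRT17 falling (-4.91). Also in A549 the nuclear-encoded subunits of respiratory complex I rose in 30 and fell in 4 of 37 cases (1.47e-06, and 0.000162 with the offset; NDUFA3 1.40), proteasome subunits rose in 25 and fell in 4 of 37 (0.000481, and 0.0115 with the offset) and aldo-keto reductases, 4 of them in the fixed lists, rose in 8 of 10 (0.00375, and 0.0317 with the offset; AKR1B1 1.07), each with adjusted p = 0.389 with an estimated correlation. Calls that ended with the offset were those of A549 mitochondrial ribosomal proteins (57 of 78 rose and 7 fell, 6.55e-07, then 0.0787), ubiquitin-specific proteases (35 of 47 fell and 4 rose, 0.000105, then 0.118) and HOX genes (17 of 28 rose and 6 fell, 0.0338, then 0.151), again with adjusted p = 0.389 with an estimated correlation. In 4T1 those of the proteasome (22 of 37 fell and 1 rose, 2.72e-05, then 0.079, and adjusted p = 0.349 with an estimated correlation) and of complex I (10 of 35 fell, 0.0278, then 0.63, and 0.526) ended too.

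The fall of interferon-stimulated genes in A549 was set against the length and GC trend. With the trend removed the list's median was -1.02, between -1.10 and -0.899 over the 9 pairs of an overexpression and a control library, which argues against the trend as the whole cause. Whether the control cells carried the empty vector is not settled. For the fall of these genes, lentiviral delivery therefore cannot be separated from added ZNF296. A hypothesis that these genes move against the ZNF296 level in every line, and so rise on knockdown, stays open: in 4T1 14 rose and 7 fell of 46 (median 0.08, quartiles -0.071 and 0.299; adjusted p = 0.156), and with the offset 18 rose and 5 fell (0.0179, but adjusted p = 0.507 with an estimated correlation). A response shared by the lines and one of the A549 cells alone cannot be told apart. The 4T1 members went both ways and the list passed in only some tests. The offset could correct only the 80.4% of 4T1 members that had a length and GC value. The rule for this hypothesis required a call in every form of the test, including an estimated correlation. No 4T1 list passed that form (adjusted p = 0.186 or more with the offset), so this rule could not decide the question. An earlier bound on the size of the median had been dropped. Since 6 libraries allow only 10 splits, no share under 0.05 can be had: the real split gave 11253 changed genes and 5 lists, the highest other split 0 genes and 4 lists, and 1 split of 10 reached the real value for each.

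The rise of ribosomal protein and mitochondrially encoded genes in A549 was set against the trend of all genes with transcript length and GC content. After the trend was removed the ribosomal median was 0.459 (0.35 to 0.624 over pairs of libraries), above the bound of 0.3 set beforehand. The trend as fitted is therefore unlikely to be the whole cause there. Length was that of each gene's longest protein-coding transcript, or its longest of any type where it had none, which can exceed that of its main one. A trend with the length of the main transcripts may thus have been removed only in part, and is not excluded. The mitochondrial median was 0.289, with pairs (0.24 to 0.374) on both sides of that bound, so for these genes a real rise and the trend cannot be told apart. In an uncentred form of the offset the pairs gave 0.303 to 0.429, all above it. RNA quality, culture state and separate preparation of the groups, on which the sources used here say nothing, could also shift short transcripts and were not tested.

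The rise of mesenchymal and matrix genes in 4T1 was weighed against fibroblasts mixed into the knockdown libraries and against the length trend. Col1a1, Col1a2, Col3a1, Dcn and Lum, abundant in fibroblasts, summed to 0.52 CPM on average in knockdown (0.516 and 0.524) and to 0.521 and 0.451 CPM in sgNTC libraries, while Col6a1 rose from 2.08 and 1.41 to 17.9 and 19.7 CPM. Of single fibroblast markers Pdgfra rose with the list (2.44 to 9.78 CPM) and Postn fell (-0.71). The list's median was 0.395 with the trend removed (0.378 to 0.464 over 4 pairs of libraries). The sum argues against fibroblasts, though Pdgfra alone does not, and the median against the trend as the whole cause; a change within the 4T1 cells is a hypothesis, and off-target effects of the single guide and culture differences stay open.

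Over 30 splits of both sets of libraries the cross-line correlation's size was 0.0812 for the real splits and at most 0.0918 for the others. The 3 others as large kept the real 4T1 split, and each other A549 split still holds part of the contrast, so these splits say nothing about chance. Genes with large changes in the same direction in both lines, picked after their values were seen, were ARHGDIB (5.28 and 1.91), PKDCC (2.82 and 2.78), BMP7 (2.29 and 2.36) and NTS (-3.08 and -1.89).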
